A study of Homo sapiens with 8 samples.

How the data were processed

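MicroRNA arrays of 8 xenograft tumours of the human colon cancer line CW-2 were analysed, 4 untreated and 4 given 30 ug galectin-9, with groups and replicate numbers taken from the labels. Per the labels' protocols, total RNA was labelled with a Toray 3D-Gene miRNA kit. The labels name Cy5 as the dye, whereas per the file headers the deposited columns belong to the 532 channel. They also name an extraction reagent for liquid samples, and a treatment of cultured cells, although the samples are called tumours. How the tumours were dosed, the scanner and its software are not given in the sources used here.

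The authors deposited the scanner output of each array as raw spot intensity, with the local background intensity beside it and no subtraction, per the file headers and values. Each array has 3200 spots, of which 2019 are miRNA probes with 1 spot each, 925 are blank, 90 carry no probe and 8 of each of 2 kinds are spike controls. The others are 24 negative controls, 32 quality-control probes and 94 probes named S-Probe, which were not used here beyond background correction. No spot was flagged. A joint name is carried by 15 probes. The deposited value table of the series holds intensity on a linear scale with a median of 230 on every array; its ranks matched those of the mean spot signal with a Spearman correlation of 0.999999. Its equal medians and maxima are those of quantile normalized values without background subtraction, which no label states. It is neither centred nor in log units.

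From the median spot signal and median local background, normexp background correction with an offset of 50 was applied to all spots in limma 3.58.1 under R 4.3.3. Control spots were then left out, arrays were quantile normalized over the 2019 miRNAs, and log2 was taken. Quantile normalization gives all arrays 1 distribution, so a global change in miRNA content cannot be seen and every fold is relative to the rest of the array. A probe counted as detected above the mean plus 2 SD of the blank spots of its array, after dropping 5% of them at each end. That threshold lay between 203 and 220 signal units, close to the median raw signal of detected probes, which was 217 to 238, so the median detected probe was only slightly above background. Spots without a probe were brighter than blank spots, and with them as reference 254 to 526 probes per array were detected. miRNAs detected on at least 4 of 8 arrays were tested, 1341 in all, whatever their group. Precision is limited by the number of arrays.

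Groups were compared with lmFit and eBayes, with group as the only term and Benjamini-Hochberg adjustment, at an adjusted p under 0.05, two-sided. Shifts of 18 miRNA lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. Lists with at least 2 tested members, 16 in all, entered the adjustment. The lists were miR-17-92 and paralogues, let-7, miR-200, p53-linked, intestinal epithelium, colorectal cancer oncomiRs, miR-15/16, miR-29, miR-30, hypoxia, fibroblast and smooth muscle, endothelium, leukocytes, erythroid cells, skeletal muscle, skin, liver, and entries resembling tRNA or rRNA. Because mature miRNAs are mostly the same in mouse and human, signals of tumour and host cells are not separated. Single values per array were compared with exact permutation tests over 70 assignments. The text names the 10 largest changes in each direction among those that passed, up to 4 of the brightest tested members of each list, the 5 brightest miRNAs, and miR-210-3p, miR-21-5p and miR-34a-5p; other names were chosen after their values were seen. List members are matched by exact name, so members under older names are outside the lists except where stated.

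Lists, tests, the rule for names and most alternatives were fixed before the data were examined. The alternatives were other background corrections and offsets, other scalings, other filters and detection thresholds, trend and robust variance, array weights, the deposited table, blocks for replicate number and slide, and leaving out each array. Mean spot signal, spots without a probe as reference, spike-control scaling, older names, position on the slide and each slide alone were chosen after seeing the data. The slide of each array was inferred from the geometry of its spot grid, which differed by at most 20 units within a slide and at least 30 between slides.

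The procedure was tested on simulated data with the means and spreads of the 1341 miRNAs and 200 changed ones in each of 20 simulations. It recovered 91.2% of 2-fold and 57.5% of 1.5-fold changes, with no wrong sign, and 6.83% of its calls were false. A changed list of 8 was called in all 20 simulations and an unchanged list in 0. These simulations leave out correlation between miRNAs, and their lists were called at an unadjusted camera p under 0.05. They plant as many rises as falls and a constant shift per array, which quantile normalization removes. The signs and false calls found there therefore do not test the choice of scaling. miRNA gene neighbours come from a RefSeq table of GRCh38.p14, used for names and neighbours only, and no genome build applies to the array files. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. GC content and probe sequences were not analysed here.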

Results

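MicroRNA (miRNA) levels were measured in xenograft tumours of CW-2, a human colon cancer cell line, on 1-colour arrays that carried 1 spot for each of 2019 human miRNA probes. The tumours formed 2 groups of 4: untreated controls, and tumours given 30 ug of galectin-9, a galactoside-binding lectin. The comparison asks how galectin-9 altered the miRNA profile of the tumour. Between 996 and 1470 probes per array lay above the blank spots of that array, and 1341 miRNAs that did so on at least 4 of the 8 arrays were tested. Array precision was limited by the 4 tumours per group. The labels do not say whether each tumour came from its own animal, so the p-values measure only the spread between these samples, which may be technical. Levels below are log2 values relative to the rest of each array, and folds include the offset of 50 signal units, which understates the change of dim miRNAs.

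After galectin-9, higher signals were measured for 4 of 9 tested let-7 family members, 5 of 14 members of miR-17-92 and its paralogue clusters, 3 of 5 members of the epithelial miR-200 family, and 2 of 3 of the miR-29 family. As lists, these families passed camera at its preset correlation and missed the threshold with an estimated correlation (camera adjusted p from 0.121 to 0.129). These results hold for quantile normalization. Without normalization the list means were -0.031 for miR-17-92, 0.16 for let-7, 0.020 for miR-200 and 0.17 for miR-29. Of these families, only let-7 then passed camera at the preset correlation. let-7a-5p (MIMAT0000062), a member of a family that represses RAS and HMGA2, rose by 1.46 ± 0.35 (SE, n = 4 per group, 2.75-fold, limma adjusted p = 0.0318). Its call was lost when each of 5 of the 8 arrays was left out, and it stood at 2.31 on slide 1 and 0.61 on slide 2. miR-34a-5p (MIMAT0000255), a direct target of p53, rose by 0.69 ± 0.15 (1.61-fold, limma adjusted p = 0.0206). The call of miR-34a-5p was lost when each of 3 of the 8 arrays was left out. Its dim relatives miR-34b-5p (0.099) and miR-34c-5p (0.093) did not pass. Lower signals fell mostly on miRNAs with numbers above 1000, led by miR-5088 and miR-4725-3p. In all, 81 miRNAs changed at a limma adjusted p under 0.05, of which 37 rose and 44 fell. These counts hold for median spot signal, normexp background correction and quantile normalization of all 8 arrays. With quantile normalization kept, 21 rose and 25 fell without background correction, and 28 rose and 7 fell with an offset of 16. With the blank mean subtracted and a floor 1 rose and 0 fell, and with mean spot signal 22 rose and 22 fell. With other scalings, 13 rose and 58 fell when scaled to miRNAs detected on all arrays, and 1 rose and 126 fell with spike controls. Without normalization 0 passed. Without galectin-9 replicate 2, 1 passed.

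The largest rise was that of miR-1260b (MIMAT0015041), whose level went from 12.17 ± 0.85 (SD, n = 4) in controls to 13.89 ± 0.50 (SD, n = 4), a change of 1.72 or 3.29-fold (limma adjusted p = 0.0191). It was followed by miR-4284 with 1.61, let-7a-5p with 1.46, miR-106a-5p with 1.34, miR-4286 with 1.32 and miR-5100 with 1.30. miR-125b-5p with 1.29, miR-1260a with 1.27, let-7c with 1.24 and miR-1273g-3p with 1.22 completed the 10 largest. Among them, miR-1260b, miR-5100 and miR-1260a are on the list of entries resembling tRNA or rRNA. The SE of these 10 changes lay between 0.16 for miR-1273g-3p and 0.35 for miR-1260b. All 4 galectin-9 tumours exceeded all 4 controls for each of them except miR-125b-5p, which their selection over the same arrays largely fixes. The groups did not overlap for 76 of the 81 miRNAs that passed, and for 154 of all 1341 tested. The smallest adjusted p of the comparison belonged to miR-1273g-3p (MIMAT0022742, limma adjusted p = 0.0041), whose call was kept when each array was left out. The calls of let-7a-5p, miR-106a-5p and miR-125b-5p were lost when each of 5 of the 8 arrays was left out. miR-106a-5p stood at 2.10 on slide 1 and 0.58 on slide 2.

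With quantile normalization falls were smaller than rises, with medians of -0.68 and 0.96, whereas without normalization the medians of the same miRNAs were -1.33 and 0.28. miR-5088 (MIMAT0021080) fell by 1.31 ± 0.33 (SE), from 11.25 ± 0.78 (SD, n = 4) to 9.94 ± 0.50 (SD, n = 4), and was, with quantile normalization, the 1 fall of at least 2-fold, against 15 such rises. miR-4725-3p fell by 0.95 ± 0.18, miR-4294 by a log2 change of -0.93, miR-3162-5p by -0.91 and miR-711 by -0.89. miR-3162-5p was detected in all 4 controls and in 2 of the 4 treated tumours. The remaining 5 of the 10 largest falls, miR-4732-5p, miR-3197, miR-1229-5p, miR-4687-3p and miR-642a-3p, ranged from -0.86 to -0.82. Among the 5 brightest miRNAs, miR-5787 changed by -0.53 and miR-6090 by -0.68, while miR-3960 stood at -0.39 and did not pass (limma adjusted p = 0.297). The call of miR-5787 was lost when each of 7 of the 8 arrays was left out, and that of miR-5088 for 6 of the 8. Of the 10 largest falls only miR-5088 overlapped between groups, with 10.24 in control replicate 1 and 10.54 in galectin-9 replicate 3. miR-4454 was the brightest probe on every array and reached the scanner limit on 6 of them, so no fold is given for it.

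**Figure D1:**
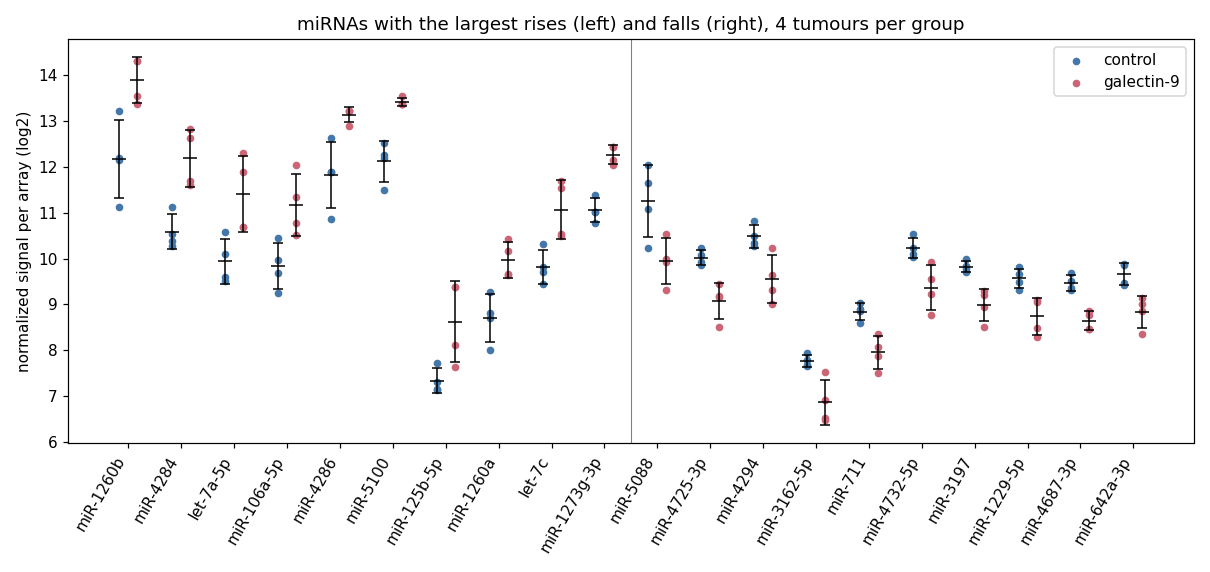
Normalized signal (log2, y axis) of the 10 miRNAs with the largest rises (left) and the 10 with the largest falls (right) in each control and galectin-9 tumour, with points for tumours and bars for the mean ± SD of 4. miR-1260b lies at 12.17 in controls and 13.89 after galectin-9, and miR-5088 at 11.25 and 9.94; scaled to spike controls, 1 miRNA passed as higher and 126 as lower.

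Of the 14 tested members of miR-17-92 and its paralogue clusters, miRNAs that promote proliferation, 5 rose and none fell. These were miR-106a-5p, miR-19b-3p with 0.97, miR-106b-5p with 0.84, miR-19a-3p with 0.81 and miR-93-5p with 0.66. miR-17-5p stood at 1.14 and missed the threshold (limma adjusted p = 0.0516). Adjusted over the list alone, 9 members rose. The list mean was 0.67 (camera adjusted p = 2.7e-08, and adjusted p = 0.129 with an estimated correlation), with 1.06 on slide 1 and 0.27 on slide 2. MIR17, MIR18A, MIR19A, MIR20A, MIR19B1 and MIR92A1 are neighbours within 10 kb in the GRCh38.p14 gene table, as are MIR106B, MIR93 and MIR25. Neighbours did not all change alike. miR-92a-3p stood at 0.08 (limma adjusted p = 0.866) and miR-25-3p at 0.36 (limma adjusted p = 0.178). Neither passed, nor did miR-18a-5p (0.68) and miR-20a-5p (0.71).

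In the let-7 family, 4 of 9 tested members rose: let-7a-5p, let-7c, let-7b-5p with 0.996 and let-7i-5p with 0.84. let-7c carries an older name on the array and is outside the list of 8, of which 7 rose when adjusted over the list alone. The list mean was 0.78 (camera adjusted p = 6.1e-06, and adjusted p = 0.129 with an estimated correlation), with 1.16 on slide 1 and 0.40 on slide 2. Members of this family, like miR-17-5p and miR-106a-5p, have near-identical sequences, so signal shared between their probes leaves the single members uncertain.

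The miR-200 family, which maintains the epithelial state by repressing ZEB1 and ZEB2, had 3 of 5 members that rose: miR-200a-3p with 1.17, miR-200b-3p with 0.96 and miR-141-3p with 0.81. miR-200c-3p, the brightest member, stood at 0.90 (limma adjusted p = 0.0538), and at 0.59 without control replicate 2. Adjusted over the list alone, 4 rose. The list mean was 0.80 (camera adjusted p = 3.7e-05, and adjusted p = 0.129 with an estimated correlation), with 1.16 on slide 1 and 0.44 on slide 2.

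Both bright members of the miR-29 family, which represses collagen genes, rose: miR-29a-3p by 1.15 ± 0.21 (SE) and miR-29b-3p by 1.03 ± 0.17. miR-29c-3p stood at 0.45 (limma adjusted p = 0.0739), and all 3 rose when adjusted over the list alone. The mean was 0.88 (camera adjusted p = 7.0e-05, and adjusted p = 0.121 with an estimated correlation), with 1.05 on slide 1 and 0.70 on slide 2. In the miR-15/16 family 1 of 6 tested members rose, miR-15a-5p with 0.56, and in the miR-30 family 1 of 5, miR-30d-5p with 0.77; the same number passed over each list alone. Their means were 0.43 (camera adjusted p = 0.0039, and adjusted p = 0.159 with an estimated correlation) and 0.52 (camera adjusted p = 0.0021, and adjusted p = 0.217 with an estimated correlation). They stood at 0.74 and 0.91 on slide 1 and at 0.11 and 0.13 on slide 2.

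Of 6 tested p53-linked miRNAs, miR-34a-5p and miR-194-5p (1.09) rose, and 3 rose over the list alone. miR-34b-5p (0.099, limma adjusted p = 0.765) and miR-34c-5p (0.093, limma adjusted p = 0.812) did not pass. Both were dim, at mean levels of 6.91 and 6.77. miR-215 (0.19, limma adjusted p = 0.742) and miR-605 (0.16, limma adjusted p = 0.691), outside the list under their older names, did not pass. miR-192-5p stood at 0.80 (limma adjusted p = 0.222) and miR-107 at 0.54 (limma adjusted p = 0.174). Without galectin-9 replicate 1, miR-192-5p stood at 0.49, and it was at 1.51 on slide 1 and 0.10 on slide 2. The mean of the p53-linked list was 0.55 (camera adjusted p = 5.4e-04, and adjusted p = 0.129 with an estimated correlation), with 0.86 on slide 1 and 0.25 on slide 2. The intestinal epithelium list shares miR-192-5p and miR-194-5p with it, and miR-215 is likewise outside it; 1 of its 6 tested members rose, miR-194-5p, and 2 over the list alone. Its mean was 0.50 (camera adjusted p = 0.0011, and adjusted p = 0.121 with an estimated correlation), with 0.75 on slide 1 and 0.25 on slide 2.

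Of 11 miRNAs listed as raised in colorectal cancer, 2 rose, miR-221-3p with 0.78 and miR-222-3p with 0.49, both repressors of the cell-cycle inhibitor CDKN1B. The call of miR-222-3p was lost when each of 7 of the 8 arrays was left out, and its sign turned under 3 other scalings, to -0.12 without normalization. miR-21-5p (MIMAT0000076), often the most abundant miRNA of colon tumours, stood at 0.88 ± 0.32 (SE) and did not pass (limma adjusted p = 0.136), and miR-155-5p stood at 0.55 (limma adjusted p = 0.105). Without galectin-9 replicate 1, miR-21-5p stood at 0.52, and it was at 1.55 on slide 1 and 0.20 on slide 2. Over the list alone 4 rose. The list mean was 0.37 (camera adjusted p = 8.6e-05, and adjusted p = 0.129 with an estimated correlation), with 0.56 on slide 1 and 0.19 on slide 2.

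Among markers of other cell types, those of fibroblasts and smooth muscle were the only list that passed camera at the preset correlation. Of 7 tested miRNAs of fibroblasts and smooth muscle, 3 rose: miR-199a-5p by 0.99 ± 0.18 (SE), miR-143-3p by 0.84 ± 0.20 and miR-145-5p by 0.82 ± 0.16, and 5 rose over the list alone. The list mean was 0.47 (camera adjusted p = 2.4e-04, and adjusted p = 0.129 with an estimated correlation), with 0.61 on slide 1 and 0.33 on slide 2. None of the erythroid miRNAs passed; their mean was -0.14 (camera adjusted p = 0.252), with miR-486-3p at -0.41. The mean was 0.14 on slide 1 and -0.43 on slide 2, where it passed (camera adjusted p = 0.0088, 2 tumours per group), and miR-451a, at 0.04 over all 8 arrays, stood at 0.83 and -0.75. The leukocyte list (mean 0.14, camera adjusted p = 0.234) and the skin list (0.27, camera adjusted p = 0.238) did not pass. The endothelial list also missed the threshold, with miR-126-3p at 0.96 and a mean of 0.55 (camera adjusted p = 0.111). The skeletal muscle mean of 0.73 (camera adjusted p = 0.218) rested on galectin-9 replicate 1, without which it was 0.03. The liver miRNA miR-122-5p was below the detection filter. The hypoxia list had no member under its listed names; miR-210, the array's older name for its first member, stood at -0.07 (limma adjusted p = 0.882).

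Entries resembling tRNA or rRNA, listed as a sign of RNA quality, went both ways. miR-1260a, miR-1260b and miR-5100 rose, miR-6087 fell by a log2 change of -0.76, and miR-3648 stood at -0.64 (limma adjusted p = 0.0765). miR-3656 stood at -0.51 and miR-3687 at -0.24, and neither passed. The mean of the 8 tested was 0.27 and the median -0.12 (camera adjusted p = 0.581), and over the list alone 3 rose and 3 fell. Because members moved in opposite directions, this test of a common shift does not show that RNA quality was alike in both groups. The 8 also include miR-4454, for which no fold is given above.

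**Figure D2:**
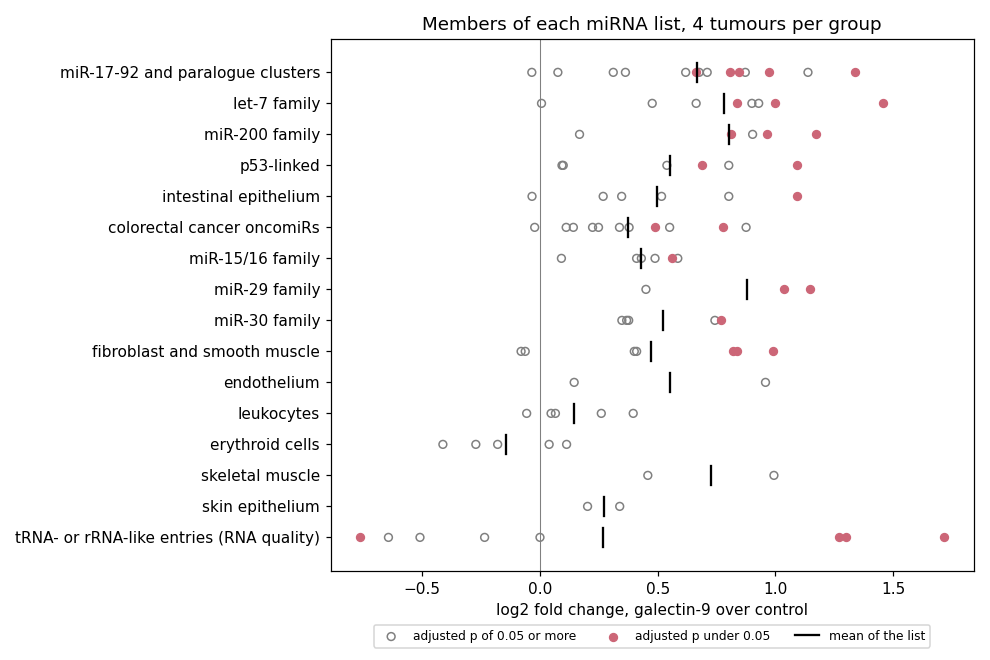
Log2 fold change (x axis, galectin-9 over control, 4 tumours per group) of each tested member of the 16 lists with at least 2 tested members, filled where the limma adjusted p was under 0.05; black bars are list means. With quantile normalization the miR-29 family has the highest mean at 0.88, and the erythroid list the lowest at -0.14. With no normalization between arrays the skeletal muscle list has the highest mean, at 0.53. The miR-17-92, p53-linked, intestinal, colorectal cancer, miR-30, leukocyte, skin, erythroid and tRNA or rRNA means then lie below 0.

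At an unadjusted p under 0.05, limma gave 244 miRNAs, against 67.05 expected by chance, with 107 higher and 137 lower; 101 of them, 52 higher and 49 lower, also changed at least 1.5-fold. The 2 directions depended on how the arrays were scaled. The 37 rises and 44 falls became 13 and 58 when arrays were scaled to the median of the miRNAs detected on all of them, 1 and 126 with spike-control scaling, and 0 and 0 without normalization or with scaling to each array's own detected miRNAs. These scalings moved the median change of all tested miRNAs from -0.01 to 0.32, -0.14, -0.15 and -0.06. Measured from that median, the 10 lists past the threshold stood between 0.38 and 0.89 with quantile normalization. They stood between -0.0037 and 0.36 with the other 4 scalings, which differ by 1 constant per array and so share these values. miR-17-92 went from 0.68 to 0.12 and miR-200 from 0.81 to 0.17. The fibroblast list alone passed camera under all 4 at the preset correlation, and missed the threshold with an estimated one (camera adjusted p = 0.129, quantile normalization). Leaving out galectin-9 replicate 2 or control replicate 3 left 1 and 2 calls, and leaving out galectin-9 replicate 1 or control replicate 2 left 21 and 25. The 81 kept their sign in each case, which their selection over all arrays largely fixes.

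The spot grids placed replicates 1 and 2 of both groups on 1 slide and replicates 3 and 4 on another. With slide as a block, 101 miRNAs changed, 44 higher and 57 lower. Slide 1 alone gave 49 higher and 57 lower, and slide 2 alone gave 0 at an adjusted p under 0.05 and 87 at an unadjusted one. Both come from 1 limma fit of all 8 arrays, with a variance shared by the slides. The median size of the 81 changes was 1.04 on slide 1 and 0.54 on slide 2. All 81 had the same sign on both, which their selection over all 8 arrays largely fixes. The interaction of slide and group passed for 0 miRNAs after adjustment in limma and for 77 at an unadjusted p under 0.05. Control arrays lay at positions 1 and 3 of a slide and galectin-9 arrays at positions 2 and 4, so group and position were not separable. With position as a random block limma gave 38 higher and 46 lower. Because each position held 1 group, such a block cannot remove a position effect that goes with the groups.

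**Figure D3:**
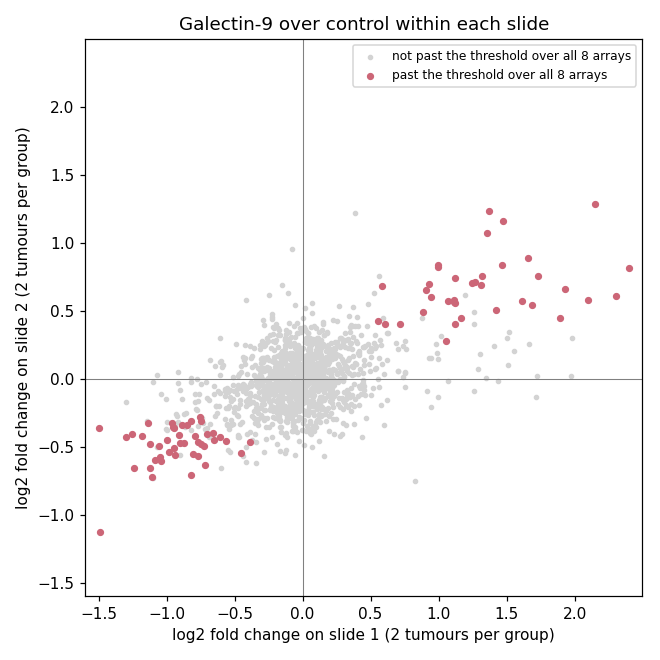
Log2 fold change (galectin-9 over control, 2 tumours per group and slide) of the 1341 tested miRNAs on slide 1 (x axis) and slide 2 (y axis), with the 81 that passed over all 8 arrays in red. Selected over both slides, all 81 have the same sign on each, with a median size of 1.04 on slide 1 and 0.54 on slide 2; without normalization between arrays 0 miRNAs passed.

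Detected probes numbered 1306 ± 135 (SD, n = 4) in controls and 1138 ± 116 (SD, n = 4) after galectin-9 (two-sided exact permutation test, p = 0.143). The median raw signal of detected probes was 231 ± 6.05 (SD, n = 4) and 224 ± 6.70 (SD, n = 4) signal units (exact permutation p = 0.2), and the smallest p this design allows is 0.0286. That median lay near the blank spots, so it says little about bright probes. The mean raw signal over all miRNA probes was 331, 656, 441 and 460 in control replicates 1 to 4. In galectin-9 replicates 1 to 4 it was 342, 328, 356 and 334, a difference that was not tested. No array pair held identical values. Pearson correlations across tested miRNAs, which are not independent replicates, had medians of 0.968 among controls, 0.958 among galectin-9 tumours and 0.944 between groups. miR-2115-5p was detected in all 4 galectin-9 tumours and in none of the controls. The reverse held for 7 miRNAs, among them miR-3615, miR-193a-5p and miR-520b, which were named after their values were seen. None of these 8 passed in limma (adjusted p of 0.0972 for miR-2115-5p and 0.124 or more for the others).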

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

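The tests of array position, of slide 1 alone, of the fibroblast rise and of splits balanced by slide, and the division at number 1000, were chosen only after the results were seen. A tumour lay far from the other 3 of its group for 14 of 184 groups of values, where chance gives about 9.2. For miR-4286, galectin-9 replicate 4 had 12.90 against 13.22 in the other 3, and for miR-5100, galectin-9 replicate 3 had 13.54 against 13.38; the other 3 arrays share 1 value because quantile normalization gave them the same rank. For miR-141-3p, galectin-9 replicate 1 had 10.54, above the next value of 10.32. For miR-378a-3p, control replicate 1 had 10.22 against 9.65 and galectin-9 replicate 3 had 9.96 against 10.37. miR-29c-3p was at 7.39 in galectin-9 replicate 2 against 7.72, miR-143-3p at 6.54 in control replicate 3 against 6.94 and miR-146a-5p at 7.28 in control replicate 2 against 7.57. miR-223-3p, a myeloid miRNA, was at 8.52 in control replicate 2 against 7.30, and miR-150-5p at 7.32 in control replicate 1 against 6.77. miR-203a, a skin miRNA, was at 8.63 in galectin-9 replicate 1 against 7.79, and miR-205-5p at 7.73 in galectin-9 replicate 3 against 6.99. miR-133b, found in skeletal muscle, was at 10.82 in galectin-9 replicate 1 against 7.01, and the mean of the muscle list there was 9.59 against 7.08.

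The 81 miRNAs that passed were 37 rises and 44 falls. Over all 35 splits of the 8 arrays into 4 and 4, the real split gave 81 calls and the highest other 0. That share is under 5% and argues against chance. The 18 splits with 2 arrays of each slide on each side, where the values are the same, are too few for a share under 5%. Chance is therefore not excluded. Quantile normalization as the whole cause is argued against for the falls, whose median was -1.33 ± 0.43 (SE) without normalization, and stays open for the rises, at 0.277 ± 0.33. Values without normalization also carry the brightness of each array. Mean raw signal over all miRNA probes was 331 to 656 in controls and 328 to 356 after galectin-9. The falls without normalization therefore do not by themselves tell a true fall from brighter control arrays. Medians of the first spike control were 13466 ± 3674 (SD, n = 4) in controls and 13128 ± 3234 after galectin-9 (exact permutation p = 0.914). Those of the second were 9978 ± 2925 and 9958 ± 2111. By the spike spots, control arrays were thus not brighter beyond the spread, and with spike-control scaling the falls had a median of -1.32. Brightness that the spike spots do not share stays open. An effect of slide 1 alone stays open. Of its 106 calls 94.3% had the same sign on slide 2, against 61.7% of all tested miRNAs, which goes against it. The 6 assignments of the slide 2 arrays (at most 78.3% in the others) are too few to decide. Of these calls, 40 also had an unadjusted limma p under 0.05 on slide 2, against 87 of all 1341. Both slides share 1 variance estimate per miRNA, so selection on slide 1 partly fixes that overlap. Array position and galectin-9 cannot be told apart, because each position held 1 group (consensus correlation within positions -0.0117), and the treatment stays open as untested.

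Entries numbered under 1000 made 30 of the 37 rises, and those at or above 1000 made 41 of the 44 falls, among 646 and 695 tested (Fisher p = 2.7e-12, which takes miRNAs as independent). The difference between the class medians was 0.145 in the real split and at most 0.129 in the other 34, which does not exclude chance, because the division was chosen from the real split. Array position stays open here as well (consensus correlation -0.0117), and GC content, which may differ between the classes, was not analysed here. Treatment stays open as untested, and the pattern is a hypothesis, found and tested on the same data.

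Of 7 tested fibroblast and smooth muscle miRNAs, 3 rose and 2 stood below 0 (miR-143-5p at -0.08 and miR-199b-5p at -0.06), with a list mean of 0.47 that missed the threshold with an estimated correlation (camera adjusted p = 0.129). All 7 were dim, at mean levels of 6.49 to 7.57 against a median of 6.75 over all tested miRNAs. A lower share of tumour cells stays open. The fibroblast list rose above the erythroid list by 0.616 ± 0.146 (SE, exact permutation p = 0.0286), but 4 of the 5 erythroid members were dim. The endothelial (0.55), skeletal muscle (0.73), skin (0.27) and leukocyte (0.14) means also stood above 0. The skeletal muscle mean was 0.03 without galectin-9 replicate 1. Without normalization skin was at -0.071 and leukocytes at -0.13, while endothelium (0.30) and skeletal muscle (0.53) stayed above 0. Fibroblasts added to unchanged tumour cells stay open too, as the list differed from the miR-200 family by -0.331 ± 0.159 (exact permutation p = 0.0857) with quantile normalization but stood above it with the 4 other scalings (0.36 against 0.17 from the median of tested miRNAs). After the values were seen, the limit was changed from 2 SE to the exact p, both explanations were renamed, and the erythroid list took the place of the miR-200 family as the test of a lower share of tumour cells, which the miR-200 value under 2 SE, with quantile normalization only, had argued against. Mature miRNAs shared by mouse and human leave the cells of origin open, and the treatment is untested.

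For the 8 miRNAs detected in all tumours of 1 group and none of the other, chance is not excluded, as 19 of 35 splits gave as many and the highest other 18. For the 10 lists past the camera threshold, chance is not excluded either, as 5 of 35 splits gave as many and the highest other 13.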

How the results depend on the processing

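Mean spot signal, spots without a probe as reference, spike-control scaling, older names, slide position and single slides were chosen after the data were seen; the other settings were planned. The cause of each change below was not tested unless stated. The 81 calls, 37 higher and 44 lower, became 46 (21 and 25) without background correction, 1 (1 and 0) with the blank mean subtracted and a floor, and 35 (28 and 7) with offset 16. They became 44 (23 and 21) with the deposited table and 44 (22 and 22) with mean spot signal. Scaling to miRNAs detected on all arrays gave 71 (13 and 58), spike-control scaling 127 (1 and 126), and scaling to each array's detected miRNAs or no normalization 0 (0 and 0), with 219 and 261 at an unadjusted p under 0.05. Slide 2 alone gave 0 (0 and 0), from 2 tumours per group. Of the 81, all kept their sign except 2 with scaling to each array's detected miRNAs and 3 without normalization or with spike controls. The kept signs are largely fixed by selection on the same arrays. Leaving out 1 array gave 1 to 99 calls, 1 to 44 higher and 0 to 56 lower; the fewest came without galectin-9 replicate 2 (1), control replicate 3 (2), galectin-9 replicate 1 (21) and control replicate 2 (25). Without control replicate 4, 24 were lower.

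Same-numbered tumours did not pair: the correlation of their deviations from the group means ran from -0.21 to 0.17, with 1 of 4 above 0.1, and 2 of 8 samples correlated best with their own number. With the replicate block 33 were higher and 23 lower, and 10 lists passed.

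Of 10 lists past the threshold, 1 remained with either scaling to detected miRNAs (fibroblasts), 2 without normalization or with spike controls (fibroblasts and let-7), where 3 passed in all with spike controls, and 0 with an estimated correlation, where the means are as reported: 0.67 for miR-17-92, 0.78 for let-7, 0.80 for miR-200, 0.55 for p53-linked, 0.50 for intestinal, 0.37 for colorectal cancer, 0.43 for miR-15/16, 0.88 for miR-29, 0.52 for miR-30 and 0.47 for fibroblasts. The miR-15/16 (0.43) and miR-30 (0.52) lists also missed it with fry, in the position block (tested with fry) and on slide 2 (0.11 and 0.13), and miR-15/16 with spots without a probe as reference (0.52). Scaled to miRNAs detected on all arrays, means past it no longer were 0.43 for miR-17-92, 0.62 for let-7, 0.49 for miR-200, 0.42 for p53-linked, 0.31 for intestinal, 0.41 for colorectal cancer, 0.47 for miR-15/16, 0.63 for miR-29 and 0.45 for miR-30. Scaled to each array's detected miRNAs they were 0.059, 0.25, 0.11, 0.042, -0.064, 0.037, 0.090, 0.26 and 0.072 in the same order. Without normalization, miR-17-92 was at -0.031, miR-200 at 0.020, p53-linked at -0.048, intestinal at -0.15, colorectal cancer at -0.053, miR-15/16 at 0.00041, miR-29 at 0.17 and miR-30 at -0.018. With spike controls these 8 were -0.026, 0.025, -0.043, -0.15, -0.048, 0.0054, 0.17 and -0.013. miR-222-3p turned to -0.035 with each array's detected miRNAs and -0.12 in both of the latter. Newly past the threshold were skeletal muscle with spike controls (0.54), endothelium on slide 1 (0.92) and the erythroid list on slide 2 (-0.43).

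Lists that missed the threshold and changed sign were the tRNA or rRNA entries (-0.015 with miRNAs detected on all arrays, -0.39 with each array's own, -0.48 without normalization and with spike controls), leukocytes (-0.040, -0.13 and -0.12 in the last 3), skin (-0.071 and -0.066 in the last 2) and erythroid cells on slide 1 (0.14). With spots without a probe as reference, 2 miRNAs instead of 8 were detected in all arrays of 1 group and none of the other. With the blank spots at 3 SD, detected probes differed by -182 (galectin-9 minus control, exact permutation p = 0.0571), and with spots without a probe as reference by -43.

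For the 39 named miRNAs past the threshold, 681 of 1090 alternative values kept direction and side, 406 kept direction only and 3 reversed; for the 35 others, 833 of 958 kept both, 43 newly passed and 82 changed sign below the threshold. Low signal over background limits the dim miRNAs most, since the median detected probe lay close to the blank spots.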

Other observations

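Some changed miRNAs outside the rule for names were chosen after their values were seen. hsa-miR-7-5p, a repressor of EGFR, rose by 1.11 ± 0.26 (SE, n = 4 per group; limma adjusted p = 0.0279), from 8.00 ± 0.28 (SD) to 9.11 ± 0.63. hsa-miR-22-3p rose by 0.93 ± 0.17 (limma adjusted p = 0.0147) and hsa-miR-24-3p by 0.91 ± 0.18 (limma adjusted p = 0.0147). hsa-miR-664b-3p rose by 0.91 ± 0.24, hsa-miR-664a-3p by 0.76 ± 0.16 and hsa-miR-3607-3p by 0.63 ± 0.14. hsa-miR-378e rose by 0.51 ± 0.11, and hsa-miR-378a-3p stood at 0.52 ± 0.17 and did not pass (limma adjusted p = 0.0972).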
